A study of Mus musculus with 8 samples.

How the data were processed

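Messenger RNA was measured by sequencing in heart tissue of C57BL/6J mice, in 4 libraries labelled Sham and 4 labelled MR, the abbreviation the series uses for mitral regurgitation. Per the labels' protocols, the frozen tissue was powdered, total RNA was extracted with TRIzol, and libraries were made with an ABclonal mRNA kit. Which part of the heart was taken, the time after surgery and the strand setting are not given in the sources used here. HISAT2 2.0.5 and the genome build mm10 are named, without roles, in the submitters' processing notes. The counting tool and the annotation release are not given in the sources used here.

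The table deposited by the authors holds whole-number read counts per Ensembl mouse gene, with a column per library and no normalization. It lists 33105 genes, of which 2500 were at 0 in every library, and no entry lacked a gene. Symbols, coordinates and exon lengths came from a GENCODE annotation of GRCm38, the assembly that mm10 names, and 32350 identifiers matched while 755 stayed without a symbol. Each column was matched to a library through its title, and the group was taken from the treatment label. The numbers in the titles form a separate block in each group, and what they stand for is not given. A difference in collection or handling that follows these blocks could not be told apart from MR. Replicate numbers only name libraries. In each library 2.27 to 2.82 times as many genes held 2 reads as held 1, a pattern that arises when both ends of a fragment are counted, so the totals may exceed the number of fragments. The labels do not state that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical.

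Total counts ran from 42291511 to 58658094 per library, so that 1 count equalled 0.0167 to 0.0237 CPM, the unit of counts scaled to a common library total. If counts are independent, a count of 0 allows up to 3 counts, or 0.0502 to 0.0711 CPM. Where both ends of a fragment are counted the floor is higher. Such floors cover counting error only. Within groups the 12 pairs of replicates differed by far more than counting noise, with chi-square values per degree of freedom of 32.1 to 42.6 over genes in the pairs with Sham replicate 1 and 12 to 28.3 in the others, and no library was a copy of another. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.9822 to 0.9911 over all pairs of libraries.

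Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 16603 genes tested and 16502 untested. Libraries were scaled by TMM, with factors of 0.967 to 1.019, and the groups were compared with the edgeR quasi-likelihood F test with robust moderation in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes past a false discovery rate of 0.05 were counted as changed. The standard error of a log2 fold change was its size divided by the square root of F. The biological coefficient of variation was 0.12. Every adjusted p of a gene in the report comes from this edgeR test unless another tool is named.

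In all, 40 gene lists with 810 members were written beforehand, and 3 members were not found in the table. The 37 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. This preset test compares a list with the other genes and treats its members as nearly independent. Camera with an estimated correlation and fry were run as alternatives. The list score of a library is the mean log2 CPM of the tested members (edgeR, prior count 2). For each list the number of members past the threshold is given over all genes and adjusted over the list alone. In addition, 20 measures per library, such as the share of mitochondrially encoded counts and the mean log2 CPM of each set of cell type markers (pseudocount 0.1), were compared by an exact two-sided permutation test with 70 arrangements, whose smallest p is 0.0286.

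The groups, tests, gene lists, naming rule and the other settings listed here were fixed before the data were examined. The genes named are 16 fixed ones, the 12 with the largest positive and the 12 with the largest negative log2 fold change among changed genes, the 5 with the lowest p in each direction, and up to 4 members of each list described, by p. The genes with the largest changes had to average at least 1 CPM and to have all MR values on one side of all Sham values, and predicted genes and immunoglobulin or T cell receptor segments were left out there. Jchain and Klf15 fall outside this rule and were chosen after their values were seen.

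The settings fixed in this way were other scalings (RLE factors computed in edgeR, library totals only), no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, no robust moderation, leaving out mitochondrially encoded genes or the top 20 genes, other thresholds, and leaving out each library in turn. Dividing the counts by 2, removing each library's trend with exon length, and leaving out libraries from the library measures were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

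The test was run on simulated counts for the same 16603 genes and library sizes, with 200 genes changed. Of 67 genes changed 1.5-fold it called 41 (61.2%), of 67 changed 2-fold 58 (86.6%) and of 66 changed 4-fold 62 (93.9%). Of 169 genes called, 8 (4.7%) were unchanged, and 0 of 40 lists of unchanged genes had a camera p under 0.05. The simulated genes varied independently and these lists were random, so this does not cover lists of correlated genes. In the real data the estimated correlation within a list reached 0.894, for oxidative phosphorylation.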

Results

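Heart transcripts were compared between mice given a minimally invasive operation that makes the mitral valve leak (MR) and mice given a Sham procedure, with 4 libraries per group. A leaking mitral valve loads the heart with extra volume. The study asked which signalling pathways take part in the resulting hypertrophy and which genes characterise it. Total counts were 44555699, 43535272, 44377167 and 46264464 in Sham replicates 1 to 4, and 49088108, 44358324, 42291511 and 58658094 in MR replicates 1 to 4. Y-linked transcripts were present in all libraries, with Ddx3y at 129 ± 8.69 CPM in Sham and 136 ± 8.04 CPM in MR (SD, n = 4).

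In a principal component analysis of log2 CPM the first component held 30.5% of the variance. Its scores were −30.1, −15.7, 7.2 and −32.4 for Sham replicates 1 to 4 and 17.6, 18, 22.8 and 12.6 for MR. Sham replicate 3 thus lay nearer to the MR libraries than to the other Sham libraries on this component. Sham replicate 1 stood apart on the second component, at 31.2 against −19.3, −6.3 and −15 in the other Sham libraries and −7 to 19.7 in MR, and had the lowest quality weight in limma-voom (0.4 against 0.76 to 1.77). Of 20 measures per library, 2 reached 0.0286, the smallest p of the exact permutation test. They were the number of genes with reads (22827 to 23298 in Sham and 23357 to 24327 in MR) and the mean log2 CPM of neutrophil markers. The lowest adjusted p was 0.286, and at least 12 measures at that smallest p would have been needed for any to pass, so the 0 past the threshold says little. Mitochondrially encoded genes took 27.4% ± 1.26 of the counts in Sham and 27.7% ± 0.709 in MR (SD, n = 4).

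**Figure D1:**
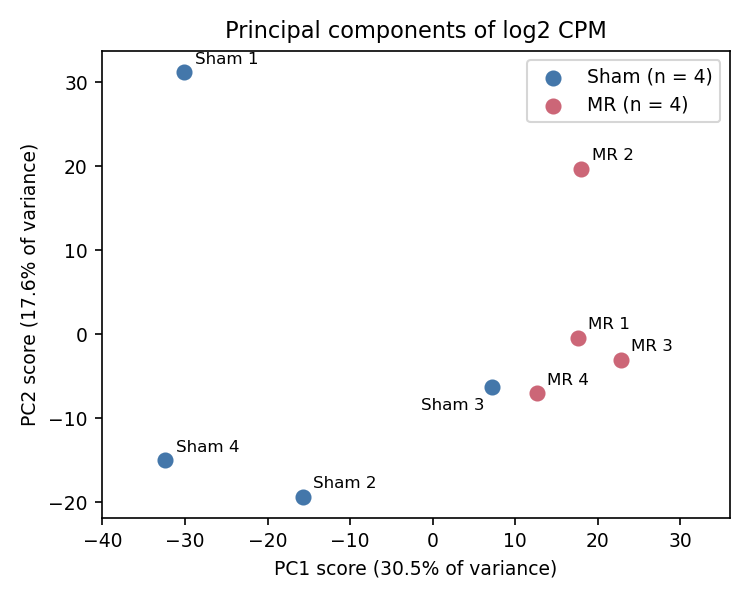
Scores of the 8 libraries on the first (30.5% of variance, horizontal) and second (17.6%, vertical) principal components of log2 CPM, with a point per library. Sham replicate 3 scores 7.2 on the first component, between the other Sham libraries and the MR libraries.

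MR hearts carried more transcript of Nppb, which encodes the B-type natriuretic peptide released by stretched heart muscle, and of 10 among 40 extracellular matrix genes. The other 30 did not pass over all genes, and the call for the list was lost with an estimated correlation (adjusted p = 0.0982). That call was kept in the directional test of fry (adjusted p = 0.0426). Ltbp2, a matrix protein that associates with elastic fibres, rose 2.97-fold, and Cilp, a cartilage-type matrix protein also made by heart fibroblasts, rose 2.52-fold. Tcf23, a helix-loop-helix transcription factor, was 2.47-fold lower, and Arrdc2, an arrestin-related gene, was 2.06-fold lower. Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell from 1550 ± 203 to 1070 ± 44.7 CPM (SD, n = 4). In all, 40 genes were higher and 36 lower in MR among 16603 tested (0.458%) in the edgeR test. Of these, 9 rose and 4 fell by at least 2-fold, and the median absolute log2 fold change was 0.62. At an unadjusted p under 0.05 there were 2502 genes, where 830 would arise by chance if genes were independent. They are not, and other splits of the same 8 libraries into 4 and 4 gave up to 2315, a split that put MR replicate 2 in the place of Sham replicate 3. The 4 MR values lay outside the range of the 4 Sham values in all 76 changed genes and in 1344 genes (8.09%) of those tested, where chance gives 2.86%.

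The number of changed genes moved when single libraries were left out. It was 93 without Sham replicate 1, 3 without Sham replicate 2, 887 without Sham replicate 3 and 6 without Sham replicate 4, and 16, 10, 14 and 41 without MR replicates 1 to 4. All 76 genes kept their sign in each of these fits, which was nearly fixed because their MR and Sham values did not overlap. Of the 41 changed genes named here, 3 (Ltbp2, Tcf23 and Ifi205) stayed past the threshold in all 8 fits. Each such fit has 3 libraries in 1 group, which weakens the test. A lost call therefore does not by itself single out the library left out. At an unadjusted p under 0.05 in edgeR these fits held 1741 to 2525 genes, but 3466 without Sham replicate 3, against 2502 with all 8. Scaling by library totals alone gave 53 higher and 17 lower (75.7% higher against 52.6%), and removing a trend with gene length, chosen after seeing the data, gave 113 higher and 190 lower (37.3%). DESeq2 called 618 genes and limma-voom with quality weights 457, with all 76 among both.

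**Figure D2:**
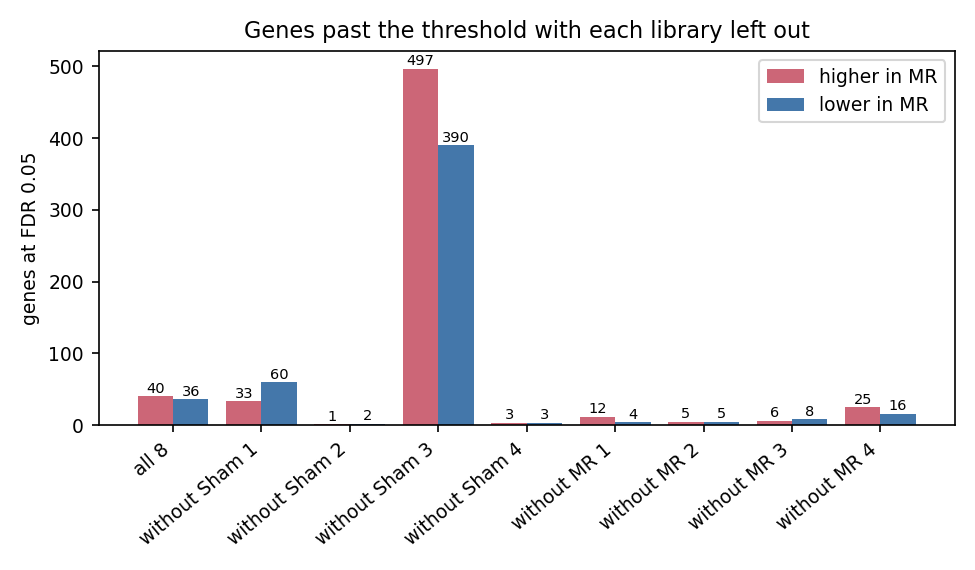
Number of genes at a false discovery rate of 0.05 that were higher or lower in MR, with all 8 libraries and with each library left out in turn. The counts run from 1 higher and 2 lower without Sham replicate 2 to 497 higher and 390 lower without Sham replicate 3.

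The 12 named genes with the largest rises included 4 matrix genes. Ltbp2 (ENSMUSG00000002020, protein-coding, chromosome 12, 84783212 to 84876532, GRCm38) rose from 2.56 ± 0.442 to 7.63 ± 1.93 CPM, with a log2 fold change of 1.57 (SE 0.18, adjusted p = 0.00871). Cilp (ENSMUSG00000042254, protein-coding, chromosome 9, 65265180 to 65280605) rose from 14.4 ± 2.58 to 36.5 ± 7.32 CPM (log2 fold change 1.34, SE 0.15, adjusted p = 0.00905). Thbs4 and Tnc, which encode the matricellular proteins thrombospondin 4 and tenascin C, had log2 fold changes of 0.88 and 1.10 (adjusted p 0.0201 and 0.0293). Ccn5, a secreted CCN family protein, rose by 0.91 (adjusted p = 0.0173). Dio2, the enzyme that activates thyroid hormone in tissues, rose by 0.94, and Clec7a, the beta-glucan receptor of myeloid cells, rose from 2.23 ± 0.309 to 4.47 ± 0.814 CPM (adjusted p = 0.0201 for both). The others were Ccdc68 at 0.88, Zfp503 at 1.01, Akap5, a kinase anchoring protein, at 1.25, Tbx15 at 1.34 and the endothelial adhesion molecule Sele at 0.85 (adjusted p 0.0293 to 0.0483). Of these 12 calls, 4 were lost without Sham replicate 1, 11 without Sham replicate 2, 0 without Sham replicate 3 and 10 without Sham replicate 4 in edgeR, with the highest adjusted p at 0.166 without Sham replicate 4. Without MR replicates 1 to 4, 7, 9, 9 and 6 were lost.

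The 12 named genes with the largest falls were led by Tcf23 (ENSMUSG00000006642, protein-coding, chromosome 5, 30968662 to 30977018), which went from 4.55 ± 0.897 to 1.84 ± 0.22 CPM (log2 fold change −1.30, SE 0.16, adjusted p = 0.00905). Ifi205 (ENSMUSG00000054203, protein-coding, chromosome 1, 174011998 to 174031810), an interferon-inducible gene with close relatives in the same cluster, went from 22.3 ± 2.86 to 11.8 ± 1.72 CPM (log2 fold change −0.91, SE 0.12, adjusted p = 0.00905). Its value is uncertain where reads match those relatives. Arrdc2 had a log2 fold change of −1.04 and Idh2 of −0.53 (adjusted p = 0.0293 for both). Rgs2, a brake on signalling through G protein-coupled receptors, fell by 0.71, and Pim3, a kinase, fell by 0.53 on the log2 scale (adjusted p 0.0293 and 0.0173). Clec10a, a lectin of macrophages and dendritic cells, was at −0.92, and Pla2g7, which encodes a phospholipase that degrades platelet-activating factor, at −0.61 (adjusted p 0.0474 and 0.0492). Lamb3, Efnb3, Tesmin and Fam107a completed the group at −0.65, −0.53, −0.93 and −0.82 (adjusted p 0.0293 to 0.0492). Of these 12 calls, 5, 10, 0 and 10 were lost without Sham replicates 1 to 4 and 10, 9, 8 and 7 without MR replicates 1 to 4, with the highest adjusted p at 0.166 without Sham replicate 4.

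Among the lowest p-values outside these groups were Nudt18 (log2 fold change 0.65, adjusted p = 0.0144) and Bcl2l1, a gene that protects cells from apoptosis (−0.51, adjusted p = 0.0113). The predicted gene Gm38372 was at 0.0676 ± 0.0239 CPM in Sham, near the floor of counting, and at 0.544 ± 0.161 CPM in MR (SD, n = 4; log2 fold change 2.94, adjusted p = 0.0144). Gm49130 was at −0.89 (adjusted p = 0.0176). It spans chromosome 14, 54940355 to 54942852, and overlaps Myh6 at 54941921 to 54966927, so its value is uncertain. Without Sham replicate 2 the adjusted p of each of these 4 was over 0.05, with a highest left-out value of 0.0678 among them. Nudt18, Bcl2l1 and Gm38372 also lost their call without Sham replicate 4, Nudt18 and Gm49130 without MR replicate 2, and Gm49130 without MR replicate 3.

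Of the cardiac stress and fetal genes, Nppb alone passed over all genes. Nppb (ENSMUSG00000029019, protein-coding, chromosome 4, 147985788 to 147987205) rose from 93.0 ± 12.3 to 166 ± 27.9 CPM (SD, n = 4; log2 fold change 0.84, SE 0.12, adjusted p = 0.020). Of 16 members tested, 1 rose, 0 fell and 15 did not pass, and adjusted over the list alone 9 were higher and 1 lower. Acta1, the skeletal muscle actin of the fetal heart, was at 205 ± 100 CPM in Sham and 714 ± 75.9 in MR (log2 fold change 1.80, adjusted p = 0.0842). The stretch-responsive genes Ankrd1 and Xirp2 were at log2 fold changes of 0.85 and 0.57 (adjusted p 0.0697 and 0.0678). Nppa, which encodes the atrial natriuretic peptide, was at 1.17 with SE 0.36 (adjusted p = 0.204), and at 0.75 to 1.31 with a library left out. Myh7, the slow myosin heavy chain, was at −0.67 with 405 ± 145 against 255 ± 14.2 CPM (adjusted p = 0.168), and its sequence is close to that of Myh6, so both are uncertain. The Myh7 value ran from −0.78 to −0.39 with a library left out. The list was higher in MR in camera (median log2 fold change 0.37, adjusted p = 7.9e-09), with an adjusted p = 0.0796 with an estimated correlation. In the directional test of fry the list had an adjusted p of 0.031. Nppb lost its call without Sham replicates 2 and 4 and MR replicates 2 and 3 (adjusted p 0.0737, 0.0762, 0.0678 and 0.051). Without Sham replicate 3, Acta1, Ankrd1 and Xirp2 passed in edgeR (adjusted p 0.00147, 0.00104 and 0.0119).

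**Figure D3:**
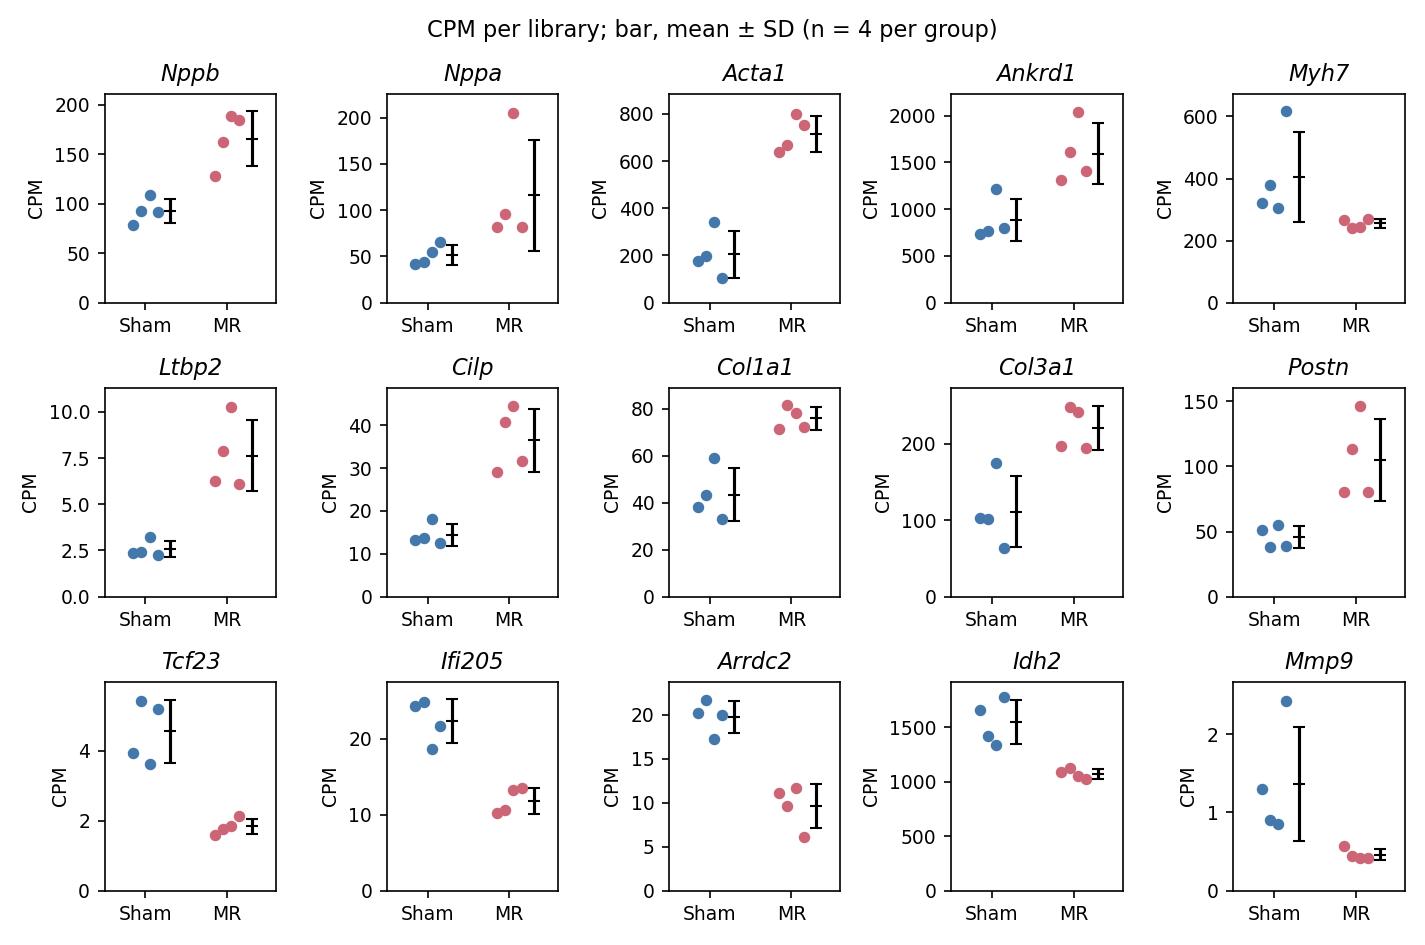
CPM of 15 genes in each library (points) with the mean and SD of each group (bars, n = 4). Nppb, Ltbp2, Cilp, Col1a1, Tcf23, Ifi205, Arrdc2 and Idh2 passed the threshold, and the others did not, such as Acta1 at an adjusted p of 0.0842.

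Genes of collagens and matrix were higher as a list in camera (median log2 fold change 0.61, adjusted p = 2.89e-48) but not with an estimated correlation (adjusted p = 0.0982). The directional test of fry gave the list an adjusted p of 0.0426. Of 40 tested, 10 rose, 0 fell and 30 did not pass over all genes, and adjusted over the list alone 34 were higher and 1 lower. Col1a1 and Col1a2, the chains of type I collagen, rose from 43.4 ± 11.2 to 75.8 ± 4.84 CPM and from 76.5 ± 10.4 to 118 ± 7.69 CPM (SD, n = 4; adjusted p 0.0483 and 0.0159). Loxl1, a crosslinking enzyme of elastin, rose by 0.52 on the log2 scale (adjusted p = 0.0201). Col3a1, the chain of type III collagen, was at 0.99 (adjusted p = 0.176), Postn, a marker of activated fibroblasts, at 1.19 (adjusted p = 0.0678), Timp1 at 0.65 (adjusted p = 0.21) and Lox at 0.18 (adjusted p = 0.671). The Lox value ran from 0.04 to 0.30 with a library left out. Among the 7 named changed genes of the list (Ltbp2, Cilp, Thbs4, Tnc, Col1a1, Col1a2 and Loxl1), 2, 6, 0 and 5 calls were lost without Sham replicates 1 to 4 and 2, 5, 5 and 2 without MR replicates 1 to 4. Without Sham replicate 3, Col3a1 and Postn passed in edgeR (adjusted p 0.00332 and 0.0355).

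In the TGF-beta pathway, which drives matrix synthesis in fibroblasts, 1 of 22 genes rose and 0 fell, and adjusted over the list alone 3 were higher and 2 lower. Tgfb3 rose by 0.53 (adjusted p = 0.0293), while Inhba was at 0.90 (adjusted p = 0.0699), Ccn2 at 0.28 (adjusted p = 0.226) and Id1 at −0.55 (adjusted p = 0.0739). The list did not pass in camera (adjusted p = 0.32). Resident fibroblast markers, whose transcripts do not count cells, held 0 changed genes among 14 (1 higher and 1 lower adjusted over the list alone), and the list was at an adjusted p = 0.221. Its lowest p-values were those of Vcan at 0.61 and Scara5 at −0.26 (adjusted p 0.0529 and 0.116). Tgfb3 lost its call without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.107). Without Sham replicate 3, Inhba, Id1, Vcan and Scara5 passed in edgeR (adjusted p 0.0481, 0.0273, 0.000973 and 0.0448).

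Ventricular sarcomere genes were lower as a list in camera (median −0.07, adjusted p = 0.00305) but not with an estimated correlation (adjusted p = 0.454). Without Sham replicate 1 the median was −0.12. Over all genes 0 of 18 changed, and adjusted over the list alone 6 were lower. Tnnt2, which encodes cardiac troponin T, was at −0.36 and Myl2, the ventricular light chain, at −0.30 (adjusted p 0.128 and 0.129), both past the threshold without Sham replicate 3 (adjusted p 0.0211 and 0.0404). Myh6, the main myosin heavy chain of the adult mouse heart, was at 23000 ± 2590 CPM in Sham and 18900 ± 1460 in MR (SD, n = 4; adjusted p = 0.163). Of 26 genes of calcium handling and ion channels 0 changed over all genes and 1 was lower adjusted over the list alone. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at −0.15 (adjusted p = 0.436) and the potassium channel gene Kcnh2 at −0.37 (adjusted p = 0.0755; 0.00217 without Sham replicate 3). That list had an adjusted p = 0.0629 in camera and passed without Sham replicate 1 (0.0101), Sham replicate 3 (0.046) and MR replicate 4 (0.0191). Z-disc and cytoskeletal stress genes had 0 of 25 changed (0 adjusted over the list alone) and an adjusted p = 0.0506. They passed without Sham replicates 1 and 4 (0.0228 and 0.0281) and MR replicates 1, 2 and 3 (0.00885, 0.0485 and 0.0462).

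In camera 4 lists of energy metabolism were lower in MR by small amounts, none of them with an estimated correlation, and 0 of their genes changed over all genes or adjusted over the list alone. Of 31 fatty acid oxidation genes, 30 had negative log2 fold changes, with a median of −0.21 (camera adjusted p = 2.43e-09, and adjusted p = 0.454 with an estimated correlation). Hadha and Acadm, which encode enzymes of beta-oxidation, were at −0.28 and −0.27 (adjusted p 0.129 and 0.163). Ppargc1a, a regulator of mitochondrial genes, was at −0.24 (adjusted p = 0.202), Pdk4 at 0.36 with SE 0.50 (adjusted p = 0.788), and Cpt1b, which overlaps a neighbouring gene and is uncertain, at −0.58 (adjusted p = 0.206). With a library left out Pdk4 ran from 0.08 to 0.66 and Cpt1b from −0.70 to −0.36. Of 47 nuclear genes of oxidative phosphorylation 45 were negative, with a median of −0.12 (camera adjusted p = 3.67e-05, and adjusted p = 0.56 with an estimated correlation). Without Sham replicate 1 this list was at an adjusted p of 0.254 with a median of −0.02, and without MR replicate 3 the median was −0.07. The complex II gene Sdha was at −0.24 (adjusted p = 0.147). Genes for branched-chain amino acid and ketone use had a median of −0.15 over 19 (camera adjusted p = 0.00114, and adjusted p = 0.454 with an estimated correlation), with Mccc1 at −0.22 (adjusted p = 0.168), and the median was −0.10 without Sham replicate 1. Glycolysis and glucose uptake genes had a median of −0.10 over 22 (camera adjusted p = 0.0119, and adjusted p = 0.454 with an estimated correlation), with Pfkfb1 at −0.57 (adjusted p = 0.147), and lost the call without Sham replicate 1 (0.053). Mitochondrially encoded genes had a median of −0.02 over 13, with 0 changed by either adjustment (camera adjusted p = 0.286; 0.0469 without Sham replicate 4). Hadha, Acadm, Sdha, Mccc1 and Pfkfb1 passed without Sham replicate 3 in edgeR (adjusted p 0.0393, 0.0417, 0.0375, 0.0443 and 0.00614).

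Neutrophil markers were lower in MR as a list in camera (median −3.68, adjusted p = 1.1e-14) but not with an estimated correlation (adjusted p = 0.312). Of 9 tested, all had negative log2 fold changes, 0 passed over all genes, and 8 were lower adjusted over the list alone. Their levels were low, with Mmp8, a neutrophil collagenase, at 1.34 ± 1.23 CPM in Sham and 0.0874 ± 0.0473 in MR (SD, n = 4; log2 fold change −3.92, adjusted p = 0.0513). Mmp9, the chemokine receptor gene Cxcr2 and Retnlg were at −1.57, −2.14 and −3.68 (adjusted p 0.0587, 0.0755 and 0.0804). All of these 4 genes passed without Sham replicate 3 (adjusted p 0.00314, 0.00869, 0.00937 and 0.0131). In the lymphocyte list 1 of 11 genes fell, Igkc, an immunoglobulin light chain gene, at −1.35 (adjusted p = 0.0293), with 1 lower adjusted over the list alone, and the list was at a camera adjusted p of 0.695. Igkc lost its call without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.114). Macrophage and monocyte markers held 0 changed genes among 20 over all genes and 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.579). The resident macrophage genes Cd163 and Mrc1 were at −0.36 and −0.29 and the lysozyme gene Lyz2 at 0.28 (adjusted p 0.0697, 0.083 and 0.102). Without Sham replicate 3, Cd163 and Lyz2 passed (adjusted p 0.0378 and, just under the threshold before rounding, 0.05).

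Interferon response genes were higher as a list, with 25 of 26 positive, 0 changed over all genes and 14 higher adjusted over the list alone. The median was 0.44, with an adjusted p = 9.09e-15 in camera and an adjusted p = 0.454 with an estimated correlation. Cxcl10, a chemokine gene, was at 1.07 and Isg15, a ubiquitin-like modifier, at 0.63 (adjusted p 0.109 and 0.119), and Isg15 passed without Sham replicate 3 (0.0259). Ifi205, named above among the falls, was not in this list. In the list of inflammatory mediators and complement 1 of 27 genes rose, Sele, and adjusted over the list alone 1 was higher and 2 lower. The complement gene C4b was at −0.85 and the chemokine gene Ccl8 at −1.54 (adjusted p 0.0873 and 0.107). Without MR replicate 2, Ccl8 passed in edgeR (0.0358). That list was at a camera adjusted p of 0.0925 and was lower with a p past the threshold without Sham replicates 2 and 3 and MR replicate 2 (0.0331, 0.0218 and 0.023). Sele lost its call without Sham replicates 1, 2 and 4 and each MR library (highest adjusted p 0.156).

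Proliferation genes were higher as a list in camera (median 0.60, adjusted p = 5.08e-08) but not with an estimated correlation (adjusted p = 0.454). The median was 0.91 without Sham replicate 3 and 0.37 without MR replicate 2. Of 32 tested, 29 were positive and 0 changed over all genes or adjusted over the list alone. Cdk1, the mitotic kinase, was at 1.07 and Mcm5, a subunit of the replication helicase, at 0.59, while Cenpf, a kinetochore gene, was at −0.69 (adjusted p 0.154, 0.155 and 0.131). Without Sham replicate 3, Mcm5 passed in edgeR (adjusted p 0.0368). Cytosolic ribosomal protein genes were lower as a list, with 41 of 42 negative and 0 changed by either adjustment (median −0.19, camera adjusted p = 8.65e-08, and adjusted p = 0.459 with an estimated correlation). Without Sham replicate 1 that median was −0.08. Rpl5 was at −0.28 (adjusted p = 0.216). Heat shock and ER chaperone genes were lower as a list, with 0 of 23 higher, 1 lower and 5 lower adjusted over the list alone (median −0.20, camera adjusted p = 1.05e-05, and adjusted p = 0.454 with an estimated correlation). Without Sham replicate 4 the chaperone median was −0.06. Herpud1, a gene of the unfolded protein response, fell by 0.50 (adjusted p = 0.0293), and the disulfide isomerase gene Pdia6 was at −0.37 (adjusted p = 0.0762; 0.0223 without Sham replicate 3). Herpud1 lost its call without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.0921).

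Neurohormonal ligands and receptors were lower as a list (median −0.10, camera adjusted p = 0.0244, and adjusted p = 0.454 with an estimated correlation). Of 21 tested, 1 fell over all genes, and adjusted over the list alone 1 was higher and 2 lower. Agtr1a, the angiotensin II receptor gene, fell by 0.34 (adjusted p = 0.0483). Corin, the protease that processes natriuretic peptides, was at −0.61 and Ace, the angiotensin-converting enzyme, at 0.35 (adjusted p 0.074 and 0.0678), and both passed without Sham replicate 3 (0.00795 and 0.0106). The median was −0.15, −0.06 and −0.05 without Sham replicates 1, 2 and 4 and −0.06 without MR replicate 2. The list lost its call without Sham replicate 2 (0.0973) and MR replicate 2 (0.0695), and Agtr1a without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.168). Immediate-early genes held 1 rise, Ccn1 at 0.59, and 1 fall, Klf4 at −0.41 (adjusted p 0.035 and 0.0474), among 24, with 6 higher and 3 lower adjusted over the list alone. Egr1 was at 1.07 (adjusted p = 0.0529; 0.0417 without Sham replicate 3). The list was at a camera adjusted p of 0.103 and passed without MR replicate 1 (0.0129). Ccn1 lost its call without Sham replicates 1, 2 and 4 and each MR library, and Klf4 without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.0989 and 0.166).

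The remaining signalling lists did not pass in camera. For PI3K-AKT-mTOR and IGF1 0 of 25 genes changed, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.695). Igf1 was at 0.43 (adjusted p = 0.0513; 0.0179 without Sham replicate 3) and Pik3r1 at −0.41 (adjusted p = 0.0879). For calcineurin, CaMK and MAPK 0 of 29 changed by either adjustment (adjusted p = 0.249; 0.0436 without Sham replicate 1). For autophagy and muscle ubiquitin ligases 1 of 20 fell, Foxo3 at −0.36 (adjusted p = 0.0483), with 2 lower adjusted over the list alone (camera adjusted p = 0.133). Foxo3 lost its call without Sham replicates 2 and 4 and each MR library (highest adjusted p 0.168). For ATF4 and the amino acid response 0 of 17 changed, with 1 lower adjusted over the list alone (adjusted p = 0.478). The circadian clock list had 0 of 18 changed by either adjustment (adjusted p = 0.0569) and passed without Sham replicate 1 (0.00481) and MR replicates 1 and 3 (0.0462 and 0.0115). Angiogenic signalling had 0 of 22 changed, with 1 higher adjusted over the list alone (adjusted p = 0.168; 0.046 without Sham replicate 3), and Angpt2, a destabiliser of vessels, was at 0.79 (adjusted p = 0.0641; 0.00618 without Sham replicate 3).

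Markers of other cell types and tissues were read beside these changes. Epicardial and mesothelial markers were higher as a list, with 8 of 8 positive and 0 changed by either adjustment (median 0.98, camera adjusted p = 0.00122, and adjusted p = 0.454 with an estimated correlation). Upk3b was at 2.08 ± 0.751 CPM in Sham and 5.74 ± 4.19 in MR (SD, n = 4; adjusted p = 0.29), and the list lost its call without MR replicate 4 (0.0784), where its median was 0.47. Valve and tendon-like markers were higher (median 0.46 over 9, 0 changed over all genes, 3 higher adjusted over the list alone, camera adjusted p = 0.00477, and adjusted p = 0.454 with an estimated correlation), with the matrix gene Cilp2 at 1.80 (adjusted p = 0.104). Their median was 0.31 without Sham replicate 2 and 0.74 without Sham replicate 4. Erythroid markers were higher (median 0.34 over 8, 0 changed by either adjustment, camera adjusted p = 0.0107, and adjusted p = 0.459 with an estimated correlation), with the haemoglobin gene Hbb-bt at 0.59 (adjusted p = 0.43). That call was lost without Sham replicates 2 and 3 and MR replicate 1 (0.114, 0.217 and 0.135), with medians of 0.22, 0.19 and 0.19, and the median was 0.52 without Sham replicate 4. Endothelial markers had a camera adjusted p of 0.0569 with 0 of 15 changed by either adjustment, and passed without Sham replicate 3 and MR replicates 1 and 4 (0.0155, 0.0382 and 0.0252). Skeletal muscle markers had an adjusted p of 0.0569 with 0 of 7 changed by either adjustment, and passed without Sham replicates 2 and 4 and MR replicates 2, 3 and 4 (0.0287, 0.00807, 0.0399, 0.0465 and 0.048). Smooth muscle and pericyte markers (0.267), Schwann cell markers (0.358), atrial markers (0.695) and sex-linked genes (0.972) did not pass in camera, and 0 of their 13, 7, 11 and 6 genes changed over all genes. Adjusted over the list alone, 2 smooth muscle and pericyte markers were higher and 1 lower, with 0 in the other 3 lists, and Cspg4 was at 0.48 (adjusted p = 0.0529; 0.00217 without Sham replicate 3). The Schwann cell list had a median of 0.09 but a negative mean of −0.10, the direction of its test. Adipocyte, lung and thymocyte markers had 4, 3 and 4 members tested, too few for a list test, with medians of 0.56, −0.69 and 0.04 and 0 changed genes.

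**Figure D4:**
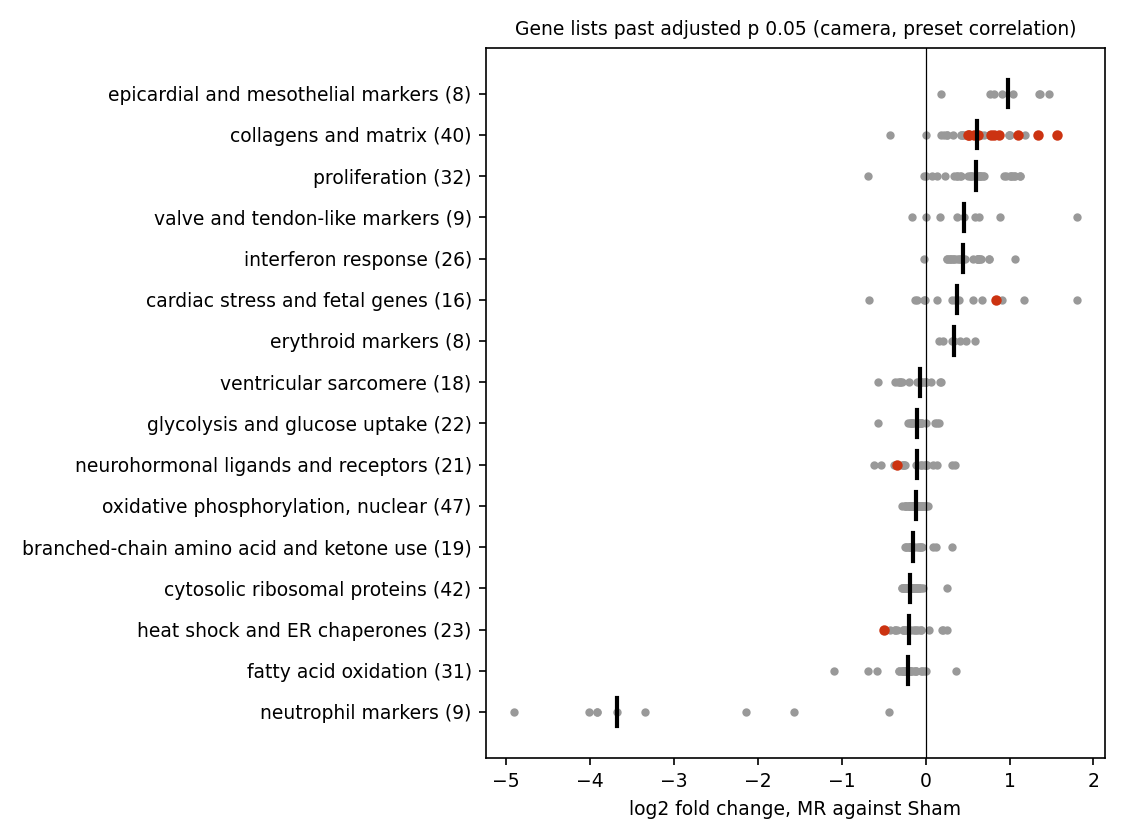
Log2 fold changes (MR against Sham, horizontal) of the members of the 16 lists past an adjusted p of 0.05 in camera with the preset correlation, with a grey point per gene, red for genes past the threshold over all genes and a bar at the median. The number of genes tested stands beside each name. The medians run from −3.68 for neutrophil markers to 0.98 for epicardial and mesothelial markers.

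Of the 37 lists tested, 16 passed in camera with the preset correlation, 7 higher and 9 lower. With an estimated correlation 0 passed, 3 had an unadjusted p under 0.05 in the same limma test, and fry counted 2 in its directional test and 27 in its mixed test, which asks whether genes change in either direction. The 2 in the directional test were the cardiac stress and fetal list (adjusted p = 0.031) and the matrix list (adjusted p = 0.0426). Sham replicate 3 lay toward MR for matrix genes, with a list score of 4.93 against 4.56, 4.60 and 4.45 in the other Sham libraries and 5.14 to 5.46 in MR.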

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

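The tests of a wrong label, of depth, of blood and of a lone Sham library were chosen only after the results were seen, while the counts over other splits of the libraries were planned. Of 272 groups of 4 libraries examined, 10 held a library far from the other 3, and chance would give about 14, or 1 in 20. Sham replicate 3 stood apart for Ankrd1, at 1220 CPM against 736 to 801 in the other Sham libraries, and for Ltbp2, at 3.22 CPM against 2.27 to 2.39. It also stood apart in mean log2 CPM for endothelial markers (6.28 against 6.12 to 6.13), and in list score for cardiac stress and fetal genes (5.42 against 5.16 to 5.2) and for angiogenic signalling (5.41 against 5.24 to 5.25). In Sham replicate 1, Timp1 was at 1.58 CPM against 1.08 to 1.13. In MR replicate 1, Agtr1a was at 40.8 CPM against 36.9 to 37. MR replicate 2 stood apart in list score for inflammatory mediators and complement (1.99 against 1.83 to 1.85) and for ribosomal proteins (6.99 against 6.81 to 6.82), and MR replicate 4 in mean log2 CPM for thymocyte markers (−1.19 against −0.97 to −0.942).

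Chance was argued against, but not excluded, for the number of changed genes, and it stayed open for the number of lists. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real split, gave 76 genes or more, and the highest other split gave 15. That share, 2.86%, is the smallest that 35 splits can give. At an unadjusted p under 0.05 the counts lay closer, with 2502 in the real split and 2315 in the highest other, and the 3 highest others each put an MR library in the place of Sham replicate 3, which points to a structure of the samples. For the lists, 6 of the 35 splits gave 16 or more past the threshold of camera with its preset correlation. The highest other split gave 20, and the median over the other splits was 11.

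Over the 500 genes ranked first by p without it, Sham replicate 3 lay toward the MR libraries, at a median position of 0.74 (bootstrap interval over genes 0.72 to 0.77), where 0 is the mean of the other Sham libraries and 1 the MR mean, against 0.26, 0.17 and −0.27 for Sham replicates 1, 2 and 4 and 0.67 to 0.96 for the MR libraries. A difference in depth is argued against by its total of 44377167, within the range of the other Sham libraries. A wrong label may explain the position and stays open, and so does a Sham heart that differed biologically, which was not tested. Against a wrong label stand Sham-like list scores of 20 glucocorticoid-responsive genes (4.63 against 4.36 to 4.43 in MR), but that list was noticed with the labels as they are and excludes nothing. Leaving this library out raised the count of changed genes to 887, which does not make that count the better one.

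Neutrophil markers were lower in MR in camera (median log2 fold change −3.68) but not with an estimated correlation (adjusted p = 0.312), and 6 of 9 did not overlap between groups. More blood left in the Sham hearts would lower the haemoglobin genes in MR as well, but their median log2 fold change was 0.40. The median of the standard errors of the single genes was 0.30. The share of counts from haemoglobin genes was 0.0525%, 0.0302%, 0.0299% and 0.0537% in Sham replicates 1 to 4. In MR replicates 1 to 4 it was 0.0703%, 0.0603%, 0.052% and 0.0369%. These genes do not measure neutrophils per amount of blood, so blood is not excluded. The neutrophil list score, like that share highest within Sham in replicates 1 and 4, was 1.70, 0.22, −0.48 and 2.59 in Sham replicates 1 to 4. It was −1.20, −1.14, −1.61 and −2.01 in MR. A lone Sham library as the whole cause is argued against, since 4 of 4 Sham libraries lay above every MR library. The size of the difference rests in part on Sham replicates 1 and 4, which lay highest, and the median ran from −3.98 to −2.73 with a library left out. Neutrophils in the tissue itself, from the operation or otherwise, may differ between the groups, which these data leave open.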

How the results depend on the processing

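The settings that divide counts by 2, remove a length trend or leave libraries out of the library measures were chosen after seeing the data, and the other settings were planned. The 76 changed genes kept their direction wherever they had a value. Since their MR and Sham values did not overlap, this was nearly fixed with a library left out. The same holds for the changed genes among the 91 counted below. The number of changed genes moved by over 1.5 times under 15 of 23 alternatives, and the number lower under 18. The former was 936 without a filter (517 higher, 419 lower), where the prior degrees of freedom became infinite against 8.01, 618 with DESeq2 (310 and 308), 457 with limma-voom and quality weights (248 and 209) and 303 with the length trend removed (113 and 190), and all 76 were among each. Scaling by library totals alone gave 17 lower, and a filter of at least 1 CPM in 4 libraries gave 20 lower. By construction, a false discovery rate of 0.01 gave 4 (2 higher, 2 lower), 0.10 gave 397 (218 and 179), and a log2 fold change of at least 1 gave 13 (9 and 4). With glmTreat of edgeR against 0.5, 0 genes passed (0 higher, 0 lower), where the plain edgeR test had 2502 genes at an unadjusted p under 0.05 and DESeq2 called 618. With a library left out the count ran from 3 to 887 (1 to 497 higher, 2 to 390 lower). RLE factors, no robust moderation, leaving out mitochondrially encoded or top 20 genes, and halved counts gave 78, 93, 80, 80 and 76. Over 91 of the genes named, Ddx3y, C4b, Ccl8 and Pik3r1 aside, 1713 results under alternatives held 1352 on the same side of the threshold, 218 that lost it, 143 that gained it and 0 with a changed direction. Except where fewer libraries or another threshold were used, the cause was not tested. For the library measures a count of 0 was nearly fixed by the design, so that it says nothing about stability. No paired analysis was possible because the replicate numbers are only names and the labels share no numbers between groups. The numbers in the titles fall in separate blocks for Sham and MR, so an effect of cohort or handling could not be told apart from MR.

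With a library left out 16 to 19 lists passed in camera, and in other settings 14 to 22. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), in the directional test of fry 2, and in its mixed test 27. The 2 in the directional test were cardiac stress (0.031) and matrix (0.0426). The adjusted p with an estimated correlation was 0.0796 for cardiac stress, 0.0982 for matrix, 0.312 for neutrophil, 0.56 for oxidative phosphorylation, 0.459 for ribosomal and erythroid, and 0.454 for sarcomere, fatty acid oxidation, glycolysis, branched-chain, proliferation, neurohormonal, interferon, chaperone, epicardial and valve lists. In the directional test of fry it was 0.187 for sarcomere, fatty acid oxidation, neurohormonal, neutrophil, interferon and valve, 0.201 for glycolysis and branched-chain, 0.24 for epicardial, 0.241 for proliferation, 0.265 for chaperone, 0.325 for ribosomal and erythroid and 0.376 for oxidative phosphorylation lists. In the mixed test calls were lost for oxidative phosphorylation (0.285), glycolysis (0.0913), proliferation (0.0896), chaperone (0.0663), ribosomal (0.237), epicardial (0.141) and erythroid (0.28) lists.

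Lists that did not pass at first passed in the mixed test of fry, which asks another question, at 0.0352 for calcium handling, 0.0201 for Z-disc, 0.000695 for TGF-beta, 0.0134 for fibroblast, 0.035 for PI3K, 0.0476 for calcineurin, endothelial and skeletal muscle, 0.0338 for angiogenic and circadian, 0.00447 for smooth muscle, 0.00204 for macrophage, 0.007 for lymphocyte, 0.0212 for inflammatory, 0.00277 for immediate-early, 0.0323 for ATF4, 0.0332 for autophagy and 0.0402 for Schwann cell lists. Without a filter calcium handling (0.0228), Z-disc (0.0206), endothelial (0.0228), inflammatory (0.0366), immediate-early (0.0414) and circadian (0.0206) lists passed. With limma-voom calcium handling (0.0088), Z-disc (0.0458), endothelial (0.0335) and circadian (0.0335) passed, with DESeq2 Z-disc and circadian (0.0468 for both), and with library totals alone Z-disc (0.0245), endothelial (0.0397) and inflammatory (0.0406). With the length trend removed calcium handling (0.00879), circadian (0.0387) and skeletal muscle (0.0295) passed, and with at least 1 CPM in 4 libraries inflammatory (0.0329). Calls were lost for erythroid markers with DESeq2 (0.0526) and for valve markers with at least 1 CPM in 4 libraries (0.0607). The direction changed, with no call on either side, for atrial markers with DESeq2 (0.975), for PI3K with limma-voom (0.741) and the length trend removed (0.791), for lymphocyte markers with the same pair (0.678 and 0.892), and for sex-linked genes without a filter (0.992), with limma-voom (0.719) and with the length trend removed (0.791). The cause was not tested.

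With a library left out the adjusted p in camera ran from 0.053 to 0.974 for atrial, 0.0101 to 0.326 for calcium handling, 0.00885 to 0.206 for Z-disc, 4.03e-08 to 0.254 for oxidative phosphorylation, 0.0469 to 0.499 for mitochondrially encoded, 0.00173 to 0.053 for glycolysis, 0.388 to 0.998 for PI3K, 0.0436 to 0.549 for calcineurin and 0.00671 to 0.0973 for neurohormonal lists. It ran from 0.046 to 0.466 for angiogenic, 0.0155 to 0.178 for endothelial, 0.206 to 0.979 for macrophage, 0.284 to 0.922 for lymphocyte, 0.0218 to 0.272 for inflammatory, 0.0129 to 0.326 for immediate-early, 0.00481 to 0.302 for circadian, 6.11e-08 to 0.0784 for epicardial, 0.00807 to 0.236 for skeletal muscle, 1.15e-05 to 0.217 for erythroid and 0.549 to 0.987 for sex-linked lists. The direction changed without Sham replicate 3 for atrial markers, without MR replicate 2 for macrophage markers, without Sham replicate 1 and MR replicate 4 for lymphocyte markers, without Sham replicate 1 and MR replicates 3 and 4 for PI3K, and without Sham replicates 1 and 3 and MR replicates 3 and 4 for sex-linked genes.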

Other observations

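The tests of Sham replicate 1 as a lone cause were chosen only after their results were seen, and so were the exact permutation tests given here. The criterion for Sham replicate 1 asked for over 75% of the median to be kept with an adjusted p under 0.05. A laxer one, over 25%, was written after the values were known and is not used. The tests of gene length, of the glucocorticoid list and of the plasma cell list were written before their results were seen, and the wording of the last pair was changed before they were run.

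Several genes known to respond to glucocorticoids were among those lower in MR. Klf15, a transcription factor of cardiac metabolism, fell by 0.49 (adjusted p = 0.0261), Arrdc2 by 1.04 (adjusted p = 0.0293) and Fam107a by 0.82 (adjusted p = 0.0492) on the log2 scale in edgeR. A list of 23 such genes was then written from general knowledge, and the other 20 were tested. Of these, 19 had negative log2 fold changes and the median was −0.28, with a lowest adjusted p of 0.0739 in edgeR. Members differed, with Fkbp5 at −0.69, Tsc22d3 at −0.28 and Zbtb16 at −0.03. In MR replicate 3, Fkbp5, Tsc22d3 and Sult1a1 lay within the range of the Sham libraries, while Sgk1 and Glul lay below it. The list score of the 20 genes was 4.74, 4.67, 4.63 and 4.86 in Sham replicates 1 to 4 and 4.36, 4.37, 4.39 and 4.43 in MR. A lower glucocorticoid response in MR may underlie this, with a camera p of 6.59e-10 (0.0019 with an estimated correlation, and 3.9e-13 to 4.64e-08 with each library left out), beside 0.0286, the smallest p that 70 arrangements can give, in an exact two-sided permutation test of the library means. Of the 20 genes, 5 are also in lists fixed beforehand whose values had been seen, the 20 were not chosen blind to the 3 that passed, and many answer to insulin, fasting or the clock as well. Hormone levels, time of day and feeding are not in the labels, so this remains a hypothesis.

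The immunoglobulin genes Igkc and Jchain were lower in MR, at −1.35 and −1.81 (adjusted p 0.0293 and 0.0483). Fewer plasma cells in MR might lower further genes of these cells, but of 16 listed 8 were tested, and of the 6 besides Igkc and Jchain 3 were negative, with a camera p of 0.797 and a p of 0.229 in the exact permutation test of the library means. Igha, Ighg2c and Mzb1 were at log2 fold changes of −1.93, −0.43 and −0.40, and Prdm1, Sdc1 and Tnfrsf13b at 0.59, 0.30 and 0.63. The further immunoglobulin genes thus also fell, but none of the 6 passed over all genes (lowest adjusted p 0.092 in edgeR, for Igha). As the 6 genes went both ways, the matter stays open.

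Fatty acid oxidation, oxidative phosphorylation and ribosomal protein lists were lower in MR in camera but not with an estimated correlation (adjusted p 0.454, 0.56 and 0.459). Sham replicate 1 differed from the other libraries in its trend with exon length, with a slope of −0.068 log2 CPM per doubling against −0.014 to 0.027. Removing the trend in each library kept 115%, 96% and 107% of the medians of the 3 lists (camera adjusted p 4.59e-09, 0.000239 and 2.7e-07). The median log2 fold change over all genes moved from 0.002 to −0.033 in that fit, so these shares include a general shift. The values argue against length as the whole cause, less clearly for oxidative phosphorylation, whose median was then only −0.11. Without Sham replicate 1 the 3 medians kept 73.8%, 21.1% and 43% (adjusted p 3.17e-07, 0.254 and 0.00944). The lower oxidative phosphorylation list may therefore rest on that library. For the other lists it stays open how far they rest on it, since both kept under 75%. Without it, the list score was 8.03, 7.83 and 8.08 in Sham against 7.59 to 7.93 in MR for fatty acid oxidation, and 6.85, 6.80 and 7.11 against 6.81 to 6.99 for ribosomal proteins, so the groups overlap. A biological difference between MR and Sham stays open as well.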
